A study of Mus musculus with 2 samples.

How the data were processed

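Gene expression was measured on 2 Affymetrix whole-transcript mouse arrays, each hybridised with RNA from spleen cells of Fx-/- mice. Fx, now named Gfus, encodes an enzyme of GDP-fucose synthesis from mannose, so mice without it depend on supplied fucose for fucosylated glycans. Per the labels, 1 array held cells of fucose-treated mice (on-fucose) and 1 array held cells of mice given no fucose (off-fucose), and both were labelled conventional type 1 dendritic cells (cDC1). Per the labels' protocols, splenocytes were depleted with beads against B220 and CD11b, and cells with CD11c were then positively selected. The series title calls the cells cDC1-enriched. RNA was labelled with the WT Pico chemistry from 9 ng of total RNA, per the labels.

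The deposited table held 1 linear intensity per probe set and array for 41345 probe sets, summarised and normalised by the authors with RMA, per the submitters' processing notes. The RMA version, software and settings and the genome build were not given in the sources used here. RMA normally returns log2 values, and log2 values had been assumed before the data were examined. The values ran from 2.74 to 9512 and were therefore read as intensities turned back from the log scale, and log2 was taken of each. The sorted log2 values of the 2 arrays differed by 0.028 on average and by 0.20 at most, as near-equal distributions do, so a shift of all genes in one direction would not be visible. Identical values on both arrays were found for 875 probe sets (2.12%).

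Gene names came from the platform annotation. Of the probe sets, 23521 had 1 gene symbol and 1814 had several, and 16010 were not listed there and are unnamed here. Symbols were set against a RefSeq gene table (assembly GRCm38.p6) by Entrez ID, which held 23328 of the probe sets with 1 symbol, and none differed. Only probe sets with 1 symbol were used for genes. Of the 22180 genes measured, 1082 had more than 1 probe set, and the one with the highest mean over both arrays stood for the gene. Other probe sets are given where they differed in direction by 0.58 or more, and for some further genes. Genes with a mean log2 intensity at or above the median of all genes (2.88) passed the expression filter, which left 11090 genes. This limit lies near the lowest intensities of the arrays, where differences are understated.

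With 1 array per group no test was possible, and no p-value or SD across replicates is given. Arrays have no read depth, and their number limits the precision. Each difference is off-fucose minus on-fucose on the log2 scale, and the counts are of genes at least 2-fold higher or lower off fucose. As a yardstick, the robust SD of the differences among genes of like expression (20 bins) ran from 0.18 to 0.38. It mixes technical and biological differences between the arrays. For 38 gene lists fixed before the data were examined (15 of cell type markers and 23 of pathways), the median difference of the members past the filter was placed among 10000 random lists of the same size matched on mean expression. A percentile from this comparison describes these arrays and is not a p-value. Of 487 distinct list members, 48 had no probe set of their own, and 17 of these, Clec9a, Cd74 and haemoglobin genes among them, were on probe sets that name several genes. To describe levels, the number of list members in the top 20% of all genes of an array was counted. The response of probe sets differs, so these counts are a description and decide nothing about the share of a cell type.

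Genes were named by a rule fixed before the data were examined. It took the 12 genes past the filter with the largest positive and the 12 with the largest negative difference, up to 4 members per list with the largest differences in size, and a fixed set with Gfus, Notch1, Notch2, cDC1 markers and housekeeping genes. Symbols of predicted genes, RIKEN clones, small RNAs, receptor families, pseudogenes and antigen receptor segments were left out of the ends. This class held 8 of the genes at least 2-fold higher and 11 of those lower. Any gene or list described as chosen after its values were seen falls outside the rule. Ifng, Foxp3, Ighm and Cd8b1 were also chosen after their values were seen. Some further list members, such as Cd3d and Ly75, are named outside the rule to describe a list. Lists of early granule genes, late granule genes, interferon-gamma-inducible GTPases, regulatory T cell genes, core MHC class II genes, Y-linked genes and genes with a Zfp symbol were made after the values were seen. Lists of further granulocyte precursor, further erythroid and further basophil genes were made after the fixed lists had been seen but before the values of their own members were looked at.

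The alternatives planned were the mean of all probe sets of a gene, no expression filter, a filter at the 67th percentile, loess of the difference on intensity (span 0.3), quantile normalisation, median centring, thresholds of 1.5-fold and 3-fold, the mean of list members, and random lists not matched on expression. A filter at a mean log2 intensity of 5 and centring on the median difference of the T cell list were added after the data were seen. The steps were tested on simulated data of 11090 genes for the comparison of off-fucose with on-fucose. Of genes given a 3-fold difference, 95% of the higher and 97% of the lower ones were called at 2-fold, and 0.138% of 10890 genes with no difference were called. Lists of 10 genes shifted by 0.5 lay above the 97.5th percentile in 99% of cases, and 4% of lists with no shift lay outside the central 95%. The simulated noise was normal and independent between genes, with the robust SD of each expression bin on these 2 arrays. Real differences spread wider (SD 0.66 against a robust SD of 0.32 in the widest bin), and genes of 1 list can vary together. These rates therefore check the steps and are not error rates of the real comparison. Work was done with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.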

Results

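The series compared spleen cells of Fx-/- mice with and without fucose supply, and asked how gene expression in cDC1-enriched cells differs when fucosylated glycans cannot be made. There was 1 array per group, so no difference below has a replicate check. Intensities ran from 2.74 to 8524 with a median of 6.99 on the on-fucose array, and from 3.15 to 9512 with a median of 7.04 on the off-fucose array. On the log2 scale these medians are 2.81 and 2.82. Across the 11090 genes past the filter, which are not independent replicates, the arrays correlated with Pearson's r of 0.973 and Spearman's rho of 0.953.

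T cell genes had high values on both arrays. All 11 measured genes of the T cell list lay in the top 20% of genes on each array, and the list's median log2 intensity was 9.79 on fucose and 9.29 off fucose. Cd3e, a chain of the T cell receptor complex, had 10.97 and 10.55, and Lef1, a transcription factor of naive T cells, had 10.42 and 10.03. Of the 18 measured cDC1 genes, 5 on fucose and 8 off fucose lay in the top 20%, and 4 of these on each array were Cd8a, Itgae, Ly75 and Id2, which T cells also express. The housekeeping list had 8 of 9 genes there on both arrays. Cd8a, carried by cDC1 and by cytotoxic T cells alike, had 8.37 and 8.22. Xcr1, the chemokine receptor that marks cDC1, had 2.90 and 3.43, near the array medians. Itgax, which encodes the CD11c used for the selection, had 3.83 and 3.86, and Zbtb46, a transcription factor of conventional dendritic cells, had 2.84 and 2.98. Itgax and Zbtb46 were chosen after their values were seen. These counts rank different probe sets, and a low value can also come from a probe set that responds poorly.

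Elane, Ctsg, Prtn3, Prss34 and Mcpt8, 5 genes of granule proteases, were among the 12 genes with the largest positive differences off fucose. At least 2-fold higher values were found for 263 genes (2.37%) and at least 2-fold lower values for 57 (0.514%), with 10770 (97.1%) within 2-fold. With differences centred on the T cell list, these counts were 427 and 27, since that centring moved the median of all genes past the filter from -0.05 to 0.20. At least 8-fold differences numbered 27 higher and 1 lower. The largest positive differences belonged to Ly6a2 (probe set 17318105; 43.6-fold), the neutrophil elastase gene Elane (41.6-fold), the cathepsin G gene Ctsg (41.4-fold), the proteinase 3 gene Prtn3 (36.2-fold), the myeloperoxidase gene Mpo (34.1-fold) and Ms4a3 (33.1-fold), a gene of granulocyte and monocyte progenitors. They were followed by Prg2, which encodes eosinophil major basic protein (27.9-fold), the basophil protease gene Prss34 (17.4-fold), the fibronectin gene Fn1 (17.0-fold), the water channel gene Aqp1 (14.7-fold), Ifitm2 (14.6-fold) and the basophil protease gene Mcpt8 (13.9-fold). Mpo (probe set 17254877) had a log2 intensity of 4.98 on fucose and 10.07 off fucose. The on-fucose values of Ms4a3 (2.68), Prtn3 (2.90), Fn1 (2.96) and Prg2 (3.13) lay near the array median of 2.81, so their folds are understated and the order among the 12 is not fixed.

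**Figure D1:**
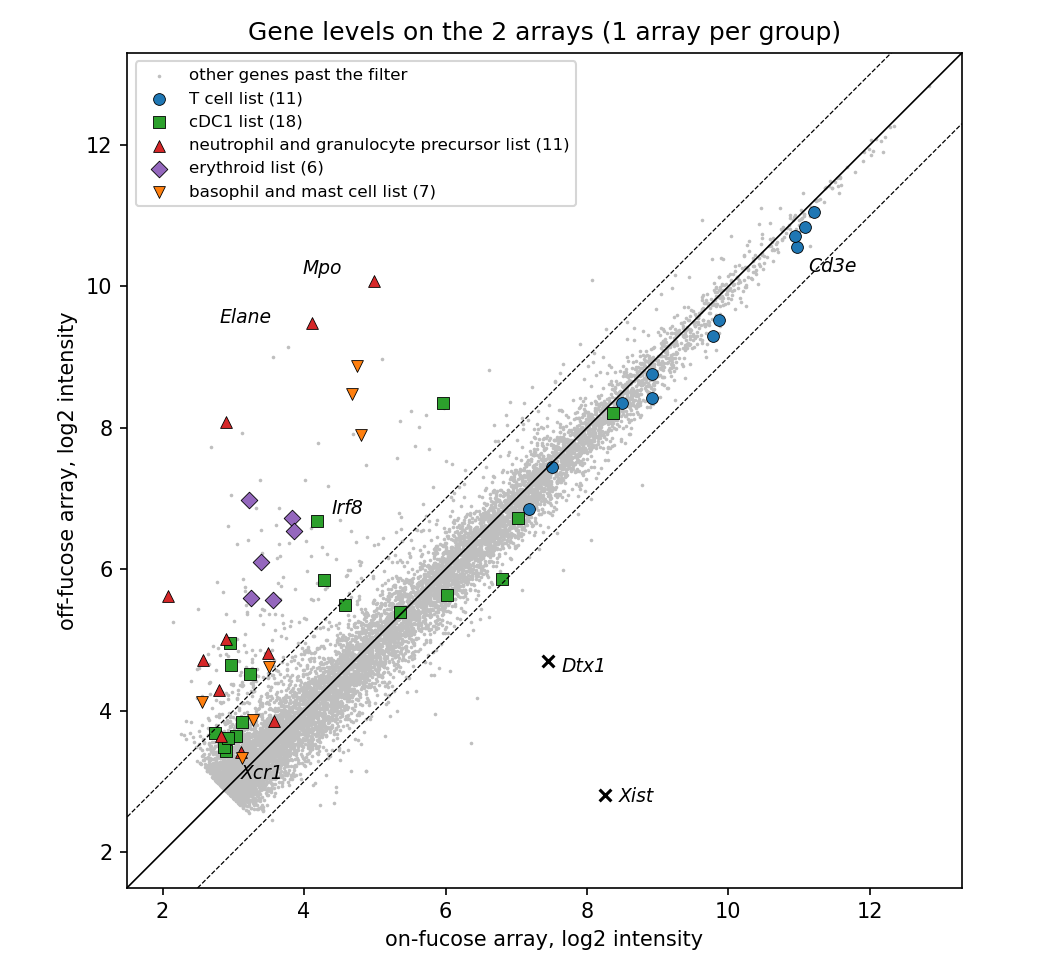
Log2 intensity of each gene past the filter on the on-fucose array (x axis) and the off-fucose array (y axis), 1 array each, with grey points for genes, coloured symbols for 5 lists, a solid line of equal values and dashed 2-fold limits. The T cell genes lie at the bright end near the line, while Mpo and Elane lie far above it and Dtx1 and Xist far below.

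Xist, the RNA that silences an X chromosome in female cells, was the gene with the largest negative difference, at 8.26 on fucose and 2.82 off fucose (probe set 17543785; -5.44). The Y-linked genes differed the other way. Uty had 2.14 and 5.26, Eif2s3y 2.34 and 3.60, and Kdm5d, at 5.44 off fucose, was at least 7.68-fold higher there. These were chosen after the value of Xist was seen. The labels used here give no sex of the mice. Next came Apol7c (-2.82) and Dtx1 (probe set 17452038; -2.74), a Deltex gene of the Notch pathway, followed by the glycolytic regulator Pfkfb3 (-1.89), Phf11c (-1.74), the MHC class Ib gene H2-M2 (-1.73), the guanylate-binding protein gene Gbp9 (-1.66) and the protease gene Asprv1 (-1.60). Klf3, a transcription factor gene, had -1.59, Rnf26 -1.56, the stress-response gene Ddit4 -1.54 and the fascin gene Fscn1 -1.51. The other 2 probe sets of Rnf26 had 0.57 and 0.06.

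Markers of several bone-marrow lineages were higher off fucose, beside the sex-linked genes that separate the arrays. All 11 genes past the filter of the neutrophil and granulocyte precursor list were higher, 8 of them at least 2-fold, with a median difference of 2.11 that lay above all 10000 random lists. The inflammatory calcium-binding protein gene S100a8 went from 2.08 on fucose to 5.62 off fucose. Of the 12 genes of the erythroid list, 6 were measured on probe sets of their own. All 6 were at least 2-fold higher, with a median of 2.70 above all random lists. Among them were the red cell anion exchanger Slc4a1 (3.76), the carbonic anhydrase Car2 (2.91), Rhag (2.72) and Ermap (2.69). The basophil and mast cell list had a median of 1.57, above all random lists, with 5 of 7 genes at least 2-fold higher and the mast cell carboxypeptidase Cpa3 at 3.09. The monocyte list had 1.49 over 4 genes, 3 of them 2-fold higher, above all random lists, with the lysozyme gene Lyz2 at 3.03. The monocyte median was 0.39 with no expression filter. The haematopoietic progenitor list had 1.03 over 5 genes (percentile 99.995; 0.58 with no filter), with the erythroid and megakaryocyte factor Gfi1b at 3.23, the surface marker gene Cd34 at least 4.60-fold higher and the stem cell factor receptor Kit at 1.03. The megakaryocyte and platelet list had 0.78 over 5 genes (percentile 99.87), with the platelet basic protein gene Ppbp at 2.27. The granulocyte list's median depended on the filter, with 1.41 for no filter and 5.18 over genes with a mean log2 intensity of at least 5, where the basophil list had 3.79. That filter takes the mean of both arrays, so genes such as Prtn3, at 2.90 on fucose and 8.08 off fucose, pass it through their off-fucose value.

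**Figure D2:**
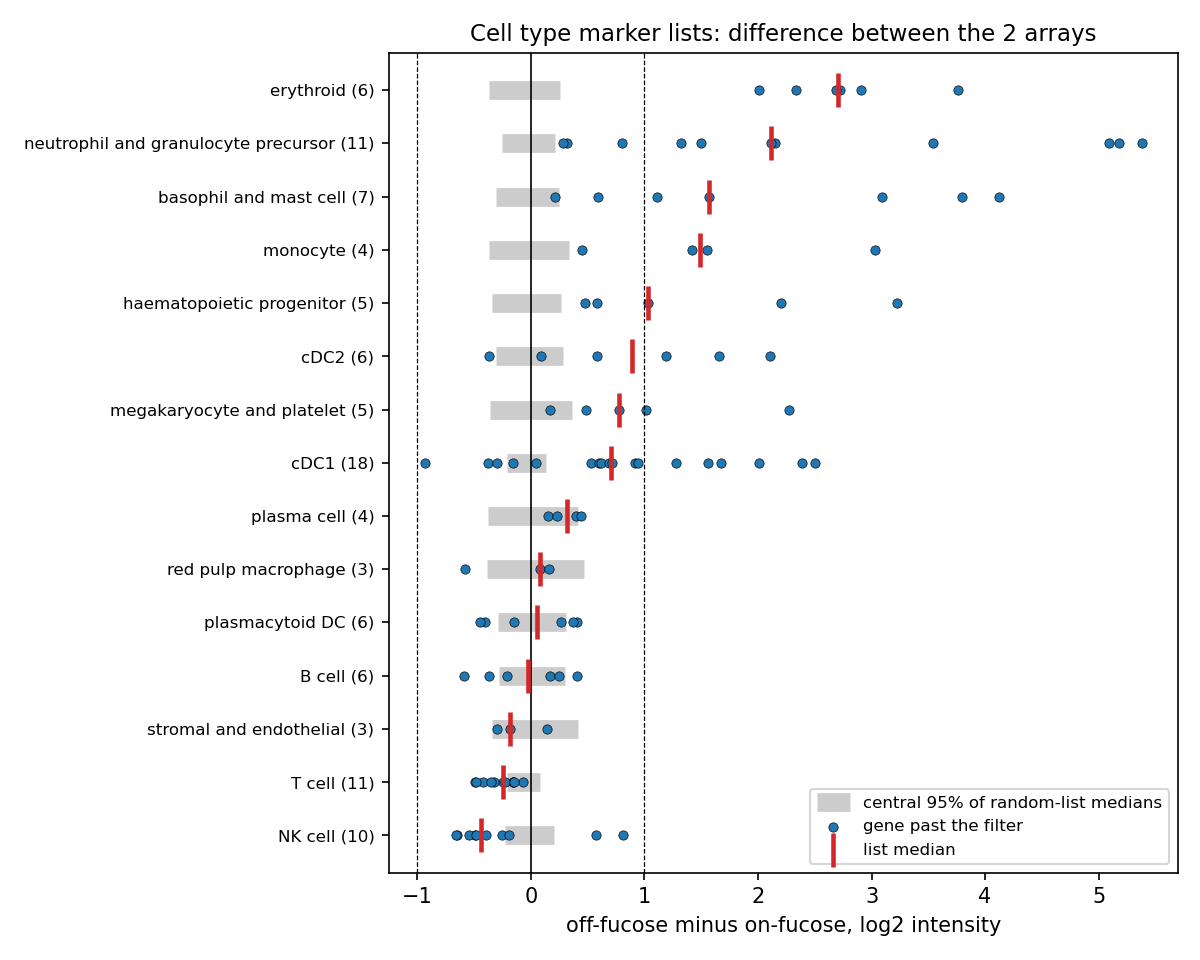
Off-fucose minus on-fucose log2 difference (x axis) of the genes past the filter in each of the 15 cell type lists, 1 array per group. Points are genes, red bars list medians, grey bars the central 95% of random-list medians and dashed lines the 2-fold limits, and the erythroid, granulocyte, basophil and monocyte medians are the highest and the NK cell median the lowest.

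Some dendritic cell genes were higher off fucose and others were not, with Itgax at 0.03 and Zbtb46 at 0.14. The cDC1 list had a median difference of 0.70 over 18 genes, above all random lists, with 6 genes at least 2-fold higher and none lower. Its largest differences were in Irf8 (5.66-fold), a transcription factor that cDC1 need and other myeloid cells also express, the lysosomal amidase gene Naaa (2.39), the endosomal RNA receptor gene Tlr3 (2.01) and Septin3 (1.67). Irf8 went from 4.18 to 6.68, while its second probe set differed by 0.21. Batf3, a factor that cDC1 require, went from 4.58 to 5.49 (0.92), whereas the endocytic receptor gene Ly75 went from 6.80 to 5.86 (-0.93) and Itgae, which encodes CD103, had -0.38. Over genes with a mean log2 intensity of at least 5, the median of the cDC1 list was 0.044, the value of Cxxc5. Cd8a, Itgae, Ly75 and Id2, which T cells also express, lay below it, and Irf8, Naaa, Wdfy4 and Batf3 lay above it. The cDC2 list had 0.89 over 6 genes (percentile 99.99), with 3 at least 2-fold higher, and 0.38 with no expression filter. Clec12a, at 2.78 on fucose, had at least 2.11, Sirpa 1.66 and Cd209a 1.19, and a second probe set of Cd209a had -0.13. The MHC class II presentation list had 0.57 over 10 genes, above all random lists, with H2-Ab1 going from 9.63 to 10.94 (1.31) and H2-Eb1 at 1.13. The plasmacytoid dendritic cell list had 0.06 (percentile 68.95), and -0.15 with no expression filter.

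Genes of dividing cells were higher off fucose, together with the precursor markers. All 21 cell cycle genes had positive differences and 13 were at least 2-fold higher, with a median of 1.25 above all random lists. Plk1, Ccna2 and Mki67, which act in or mark dividing cells, had 2.18, 2.18 and 2.17, and Birc5, at 2.48 on fucose, had at least 2.10. The immediate early and cell handling list, which holds genes known to respond within the hour to tissue dissociation, had 0.76 over 13 genes, also above all random lists. The heat shock genes Hspa1b (2.31) and Hspa1a (4.58-fold) and the orphan receptor gene Nr4a1 (1.10) had its largest differences. The unfolded protein response list had 0.28, with all 12 genes positive (percentile 99.99) and Sdf2l1, an endoplasmic reticulum protein gene, at 1.56.

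Most genes of fucose synthesis and salvage had lower values off fucose, each within 2-fold. Gfus itself (probe set 17318232) had 4.89 on fucose and 4.50 off fucose, a difference of -0.39. Both arrays come from Fx-/- mice and no wild-type array was used here, so this value does not check the genotype. The list of GDP-fucose synthesis and salvage had a median of -0.33 over 9 genes (percentile 0.76), 7 of them negative, and -0.092 with centring on the T cell list. The GDP-fucose transporter gene Slc35c1 had -0.56, the fucokinase gene Fcsk -0.55 and Gmds -0.38. The fucosyltransferase list had -0.05 (percentile 50.68), or 0.19 with that centring, with Pofut2, a protein O-fucosyltransferase gene, at -0.69, and the selectin ligand list had 0.03 (percentile 76.86).

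Dtx1 was the largest difference among Notch pathway genes. It went from 7.45 to 4.70, which is 6.70-fold lower, and its second probe set went from 3.99 to 3.19 (-0.80). Notch receptors carry O-fucose that their ligand binding depends on. The Notch target list had a median of -0.28 over 5 genes (percentile 4.3), with Myc at -0.34, Il2ra at -0.28 and Nrarp at 0.26. Its mean was -0.67, and its median was -0.041 with centring on the T cell list. The list of Notch receptors and machinery had -0.22 over 14 genes (percentile 2.56), none of them 2-fold apart. Its median was -0.11 with no expression filter and 0.02 with centring on the T cell list. Notch1 went from 7.50 to 7.10, Notch2 from 8.55 to 8.83, and Lfng, a glycosyltransferase that extends O-fucose on Notch, from 8.25 to 7.54. The Wnt and beta-catenin list had -0.34 over 9 genes (percentile 0.71; -0.099 with centring on the T cell list) and a mean of -0.16. Its coreceptor gene Lrp5 had 0.84, the adenomatous polyposis coli gene Apc -0.48 and the beta-catenin gene Ctnnb1 -0.47.

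Most genes of the T cell and interferon-stimulated lists had lower values off fucose, each within 2-fold. The T cell list had -0.24 (percentile 0.73), with all 11 genes negative by at most 0.50 in size. Among random lists not matched on expression it lay at percentile 2.92, inside the central 95%. The NK cell list had a median of -0.44 over 10 genes, below all random lists, with a mean of -0.23 and a median of -0.20 with centring on the T cell list. Its members went both ways. The activating receptor gene Klrk1, at 2.69 on fucose, had at least 0.81, and Ncr1, another such gene, had 0.57. The transcription factor gene Tbx21 had -0.66 and the perforin gene Prf1 -0.65. The interferon-stimulated list had -0.44 over 14 genes (percentile 0.02), with 13 negative and none 2-fold apart, and -0.20 with that centring. Its largest differences were in Stat2 (-0.74), the RNA sensor gene Ddx58 (-0.73), Usp18 (-0.58) and Ifit2 (-0.55). The co-stimulation and DC maturation list had -0.24 over 10 genes (percentile 2.49), which turned to 0.0072 with centring on the T cell list. It lay at percentile 3.6 among unmatched random lists, again inside the central 95%.

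Other lists lay within the central 95% of random lists. With centring on the T cell list, the medians of cytokines (0.080), chemokine receptors (0.068), MHC class I (0.073), sterol synthesis (0.029), stromal genes (0.060), B cells (0.22), NF-kappaB (0.24), glycolysis (0.24) and ribosomal proteins (0.22) turned positive. The cytokine and chemokine list had a median of -0.16 and a mean of 0.22 (percentile 11.67), with the chemokine genes Ccl3 at 2.85 and Ccl4 at 1.32, Il1b at 1.29, and Cxcl16 at -1.01. The chemokine receptor and migration list had a median of -0.18 and a mean of 0.04 (percentile 6.425), and the MHC class I and cross-presentation list -0.17 and 0.07 (percentile 6.44), with the oxidase gene Cybb at 2.54. The co-inhibition list had 0.16 (percentile 96.21), with the inhibitory receptor gene Lilrb4a at 2.49, Cd200 at -0.84 and Cd274, which encodes PD-L1, at -0.81. The Toll-like receptor list had 0.01 (percentile 73.53), with the trafficking chaperone gene Unc93b1 at 1.64. The NF-kappaB list had -0.0048 (percentile 78.655), with the inhibitor gene Tnfaip3 at 1.34. The sterol synthesis list had -0.21 (percentile 6.61), glycolysis a median of -0.0068 and a mean of 0.07 (percentile 73.57), oxidative phosphorylation 0.05 (percentile 96.115) and the cytosolic ribosomal proteins -0.03 (percentile 66.355). Among cell types, the B cell list had -0.02 (percentile 46.28), plasma cells 0.31 (percentile 95.41), and stromal and endothelial cells -0.18 (percentile 13.925). Red pulp macrophages had a median of 0.08 and a mean of -0.11 over 3 genes (percentile 67.39). The 9 housekeeping genes ran from -0.23 in Ywhaz to 0.16 in Rplp0, with a median of 0.02 and a mean of -0.0090 (percentile 81.875).

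**Figure D3:**
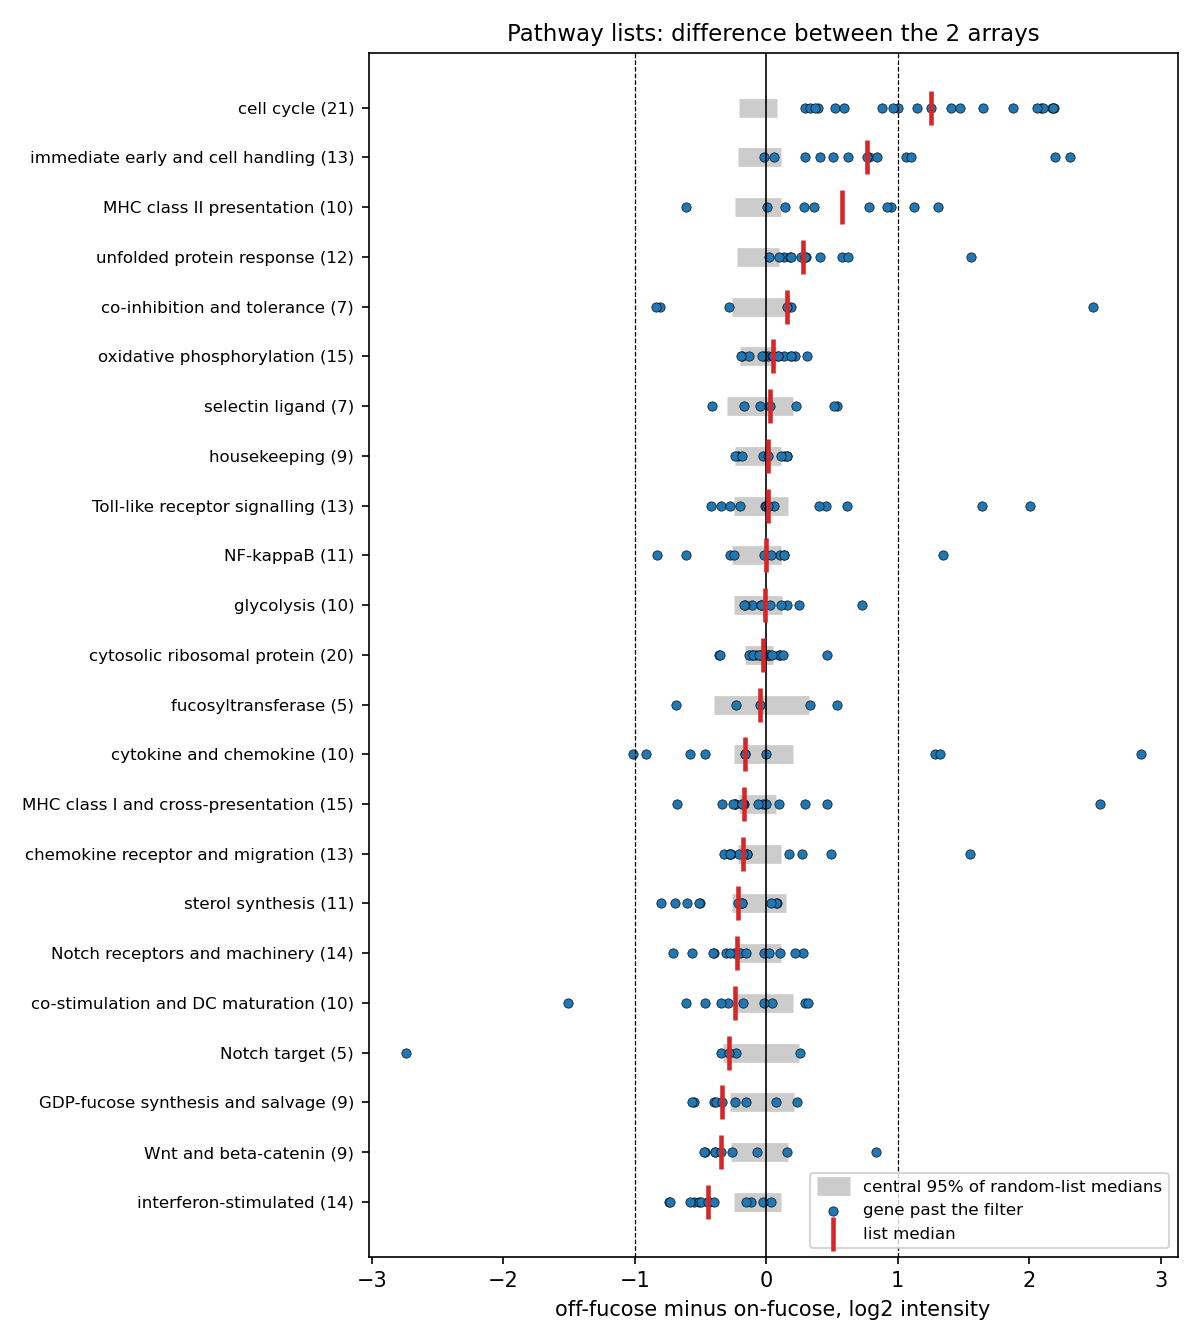
Off-fucose minus on-fucose log2 difference (x axis) of the genes past the filter in each of the 23 pathway lists, 1 array per group. Points are genes, red bars list medians, grey bars the central 95% of random-list medians and dashed lines the 2-fold limits, and cell cycle has the highest median at 1.25, and Dtx1 at -2.74 is the lowest point in the Notch target list.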

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

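Probe sets without a single gene symbol were outside the comparison of genes and also held differences. Of 7447 such probe sets past the same intensity limit, 324 were at least 2-fold higher and 537 at least 2-fold lower off fucose. Here the lower ones outnumbered the higher ones, whereas among named genes 263 were higher and 57 lower. They stay unnamed here, and no explanation was tested for them.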

How the results depend on the processing

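The filter at a mean log2 intensity of 5 and the centring on the T cell list were chosen after seeing the data, and the other settings were planned. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Low signal over background limits the differences of dim genes. The counts of genes at least 2-fold higher and lower (263 and 57) stayed within 1.5 times under quantile normalisation, loess, median centring, the mean of probe sets, no filter and the filter at the 67th percentile. The same 263 higher genes and 47 of the lower ones were called after quantile normalisation, 263 and 43 after loess, and 263 and 50 after median centring. The counts were 640 and 473 at 1.5-fold, 118 and 12 at 3-fold, 97 and 25 at a mean of 5 or more, and 427 and 27 with T cell centring. At the higher thresholds and filters fewer genes can pass. The centring subtracts 1 value from each difference, and the cause of the other shifts was not tested.

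With T cell centring, the medians of 12 lists changed sign, and among lists outside the central 95% of random lists the only one was co-stimulation, at 0.0072. Other lists outside that range had -0.092 for GDP-fucose synthesis, -0.099 for Wnt, -0.20 for NK cell and interferon-stimulated genes, 0.94 for cDC1, 1.13 for cDC2, 0.82 for MHC class II, 2.36 for granulocyte precursors, 1.73 for monocytes, 2.95 for erythroid, 1.02 for megakaryocyte, 1.81 for basophil, 1.27 for progenitor, 1.49 for cell cycle, 0.52 for unfolded protein response and 1.01 for immediate early genes. With the 67th percentile filter they were 0.92 for cDC1, 1.43 for cDC2, -0.57 for NK cells, 4.32 for granulocyte precursors, 3.44 for basophils, 0.78 for MHC class II and -0.40 for co-stimulation. At a mean of 5 or more they were 0.044 for cDC1, 5.18 for granulocyte precursors, 2.91 for erythroid, 3.79 for basophils, 0.78 for MHC class II and 0.98 for cell cycle. With no filter they were 0.38 for cDC2, 1.41 for granulocyte precursors, 0.39 for monocytes, 0.58 for progenitors and 0.78 for MHC class II. The mean of list members was 0.82 for cDC1, -0.23 for NK cells, 2.52 for granulocyte precursors, 2.07 for basophils, 1.504 for progenitors, -0.16 for Wnt and 0.39 for unfolded protein response. The cDC2 list had 0.56 with the mean of probe sets, and cell cycle had 1.33 with loess. Against unmatched random lists, the T cell list lay at percentile 2.92 and co-stimulation at 3.6, both then inside the central 95%.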

Other observations

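The tests of T cell and cDC1 shares, a lower T cell share, scaling, sex and Dtx1 were chosen after the values were seen, and only the tests on the 3 lists of further precursor genes were chosen before their members' values were looked at.

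Several genes of interferon-gamma-inducible GTPases, which restrict intracellular pathogens, had lower values off fucose. The list was made after Gbp9, one of its members, was seen, so its values only describe it. Its 12 genes past the filter had a median difference of -0.83, with 5 at least 2-fold lower. Irgm2 had -1.25, Gm12250 -1.24, Iigp1 -1.12 and Gbp10 -1.09, while Gbp3 had 0.34. The gene of interferon gamma itself, Ifng, had 3.01 on fucose and 3.75 off fucose.

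The 230 genes with a Zfp symbol, most of which encode zinc finger transcription factors, had a median difference of -0.17, which turned to 0.07 relative to the T cell list. The regulatory T cell genes had -0.12, with Foxp3 at 6.65 on fucose and 6.60 off fucose. Ighm, the immunoglobulin heavy chain of IgM, had 11.53 on both arrays in the brightest of its 7 probe sets. The B cell list, in contrast, had a median log2 intensity of 3.20 on fucose and 2.92 off fucose. Cd8b1, a chain of the CD8 receptor on T cells, had 10.95 and 10.81. The early granule genes had a median of 5.18 with 5 of 5 at least 2-fold higher, the late granule genes 1.15 over 4 genes (2 higher), the core MHC class II genes 1.04 and the Y-linked genes 2.94. These granule, MHC class II and Y-linked lists were made after the values were seen, so their medians and counts only describe them. All early granule genes are among the 12 genes with the largest positive differences.

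T cell transcripts had high values on both arrays labelled cDC1. At most 44.4% of the cDC1 list lay in the top 20% of genes on either array, and 100% of the T cell list did on both. Cd3d had 11.20 and 11.05, and the T cell list's median log2 intensity was 9.79 on fucose and 9.29 off fucose. The array medians were 2.81 and 2.82. These T cell values argue against cDC1 as the only source of the RNA on either array. Whether T cells or cDC1 formed most of the cells cannot be told apart, because these shares rank different probe sets and no array of known makeup was analysed here. Depletion of B220 and CD11b would leave T cells in, selection for CD11c would remove most of them, and 4 genes of the cDC1 list (Cd8a, Itgae, Id2 and Ly75) are also expressed by T cells. An exchange of the on-fucose and off-fucose labels was not tested.

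The granulocyte, red cell and basophil precursor genes were higher off fucose. A lower share of T cells alone would raise the genes of all other types alike. Here the lowest erythroid difference exceeded the highest core MHC class II difference by 0.71. This comparison was chosen after both sets of values had been seen, so it describes them and does not decide the question. No housekeeping gene differed by more than 0.23 in size. The arrays had been normalised to near-equal distributions, which keeps most genes near 0 whatever the scaling, so this value cannot decide about scaling. Further erythroid genes had a median of 1.11 (9 of 16 at least 2-fold higher), which is consistent with red cell precursors off fucose, where Slc4a1 had a log2 intensity of 6.98 and Car2 of 6.73. Further granulocyte genes had 0.499 (11 of 12 positive, 3 of them 2-fold, above all random lists). Further basophil genes had 0.479 (7 of 8 positive, 1 of them 2-fold, percentile 99.92). Both lay below the limit of 0.5 set in advance for ruling such cells out, so by that rule both predictions failed. The shortfall was less than the SD of random lists (0.095 and 0.12), a margin that was not part of the predictions. No conclusion on these sources is drawn (Mpo at 10.07 off fucose). Selection for CD11c would by design remove most red cell precursors, granulocyte precursors and basophils, and depletion of CD11b mature granulocytes. How far it did so here is not known. Cd3d of T cells, which that selection would also remove, had 11.20 on fucose and 11.05 off fucose. Xist differed by -5.44, so fucose supply and animals of a different sex cannot be told apart with 1 array each, and an effect of fucose on blood cell formation stays an untested hypothesis.

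Dtx1 differed by -2.74 off fucose in its brighter probe set and by -0.80 in its dimmer one. The first is 5.54 times the largest negative difference of a T cell gene (-0.50). This argues against a lower share of T cells as a whole being the only cause for that probe set. A lower share of only some T cells was not tested. The dimmer one does not reach 2 times the largest negative difference of a T cell gene, and excludes nothing. This limit was set after the values were seen. Lower Notch signalling may be a candidate explanation that cannot be told apart here, because only 2 other target genes had a mean log2 intensity of 5 or more. These were Myc (-0.34) and Il2ra (-0.28), which fell further than the T cell list's median (-0.24), but 0 of them fell further than its largest negative difference (-0.50). Animal and sex differ between the arrays as well.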
